A study of Mus musculus with 2 samples.

How the data were processed

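RNA was measured in 2 total RNA libraries of mouse gastrocnemius, which form 1 group of 2 biological replicates per the labels. Both mice were males 10 days old. The labels give the mice different animal numbers but the same donor code. RNA was extracted with a column-based tissue kit from Norgen and spiked with ERCC RNAs, per the labels, which name a spike profile made for stranded libraries with reduced ribosomal RNA. Whether counting used the strand is not given in the sources used here, so genes with an antisense partner are uncertain.

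The deposited gene and transcript tables hold expected counts, posterior mean counts and TPM in the column layout of RSEM, made from transcriptome alignments on mm10 with GENCODE M21, per the file headers and accompanying notes. The deposited TPM values are scaled over all features, spike-ins and mitochondrial genes included. The deposited transcript table also gives each transcript's percent of its gene. The effective lengths in the gene tables imply a fragment length of 100. A second deposited transcript table, in the column layout of kallisto, holds estimated counts and TPM derived from a FASTQ file. Its effective lengths imply mean fragment lengths of 347 in replicate 1 and 355 in replicate 2. The aligner and the program versions are not given in the sources used here. The different treatment of fragment length affects short genes, so TPM of short RNAs is the least certain.

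The gene tables list 81881 features, of which 55536 matched GENCODE M21 genes. A further 26248 features with a bare number as identifier summed to 0.96 and 1.97 counts. These, the 96 spike-ins and the phiX control were left out of the library sizes used for scaling and of all comparisons of genes. Over all features the libraries held 38874862 and 38160786 expected counts. Spike-ins took 0.741% and 0.735%. The second tables held 37386161 and 36335649 estimated counts. Genes that they do not list were left out of the comparison between the tables. Of the symbols in the gene lists, 3 had no match (Hbb-b1, Ahsp and Cyr61). Where a symbol had several genes, that with the highest mean count was used. Reads shared by copies or overlapping genes make a gene uncertain, and ratios that differed by over 0.5 on the log2 scale between the 2 tables are named so.

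Expected counts were rounded to whole numbers for edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3. Libraries were scaled with TMM over endogenous genes with a mean count of 10 or more. The log2 ratio of replicate 2 over replicate 1 used a prior count of 0.5. Intervals of 95% for the ratio of a gene or of a summed count are exact binomial intervals of the rounded counts and cover counting error only, since reads without molecular identifiers are not independent molecules. A gene list was compared by the median ratio of members with a mean expected count of 20 or more, where at least 4 had one, against 10000 random lists of equal size matched on mean expression in 25 bins. Intervals of a list median, and of a difference of medians, are 95% bootstrap intervals from 2000 resamples of the genes, and they describe the spread over genes. Two-sided shares were adjusted over the lists that could be compared with the Benjamini-Hochberg method. Isoform ratios used a pseudocount of 0.1 TPM and the correlation across genes a pseudocount of 1. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

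The comparisons were tested on simulated data. Dispersion was recovered as 0.0503, 0.0997 and 0.199 for simulated values of 0.05, 0.1 and 0.2 over 16214 genes. For the list comparison on 14667 genes with 200 genes shifted, 4 of 4 lists shifted by 0.2, 3 of 3 shifted by 0.4 and 3 of 3 shifted by 0.8 were called, and 0 of 10 unshifted lists. The largest error of a recovered median was 0.0815 for unshifted lists and 0.161 for lists shifted by 0.4.

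The gene lists, the comparisons of the libraries, most alternatives and the rule for named genes were fixed before the data were examined. The tests of explanations for patterns were written after those patterns had been seen. Named are the 20 protein-coding genes with the highest mean TPM, members of each list (all of a list of up to 6, otherwise the 3 highest and the member with the largest ratio), the genes of the isoform pairs, the 10 largest and 10 smallest ratios among protein-coding genes with a mean expected count of 100 or more, 5 genes each way between the tables, and the leading transcripts. Not all of these are given with their values, and some further list members are named as examples after their values were seen. Alternatives covered the second table, scaling by DESeq2 size factors, library totals and spike-in totals, posterior mean counts, filters on low counts, pseudocounts, means in place of medians and leaving out each replicate. Of the alternatives, 3 were added after seeing the data: TPM without the 7SL genes, list ratios with a trend on length and GC content removed, and tables scaled to the same median.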

Results

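Total RNA was sequenced from the gastrocnemius, the large calf muscle, of 10-day-old male mice of the B6CASTF1/J hybrid strain. There was 1 group of 2 libraries, 1 per mouse, each made from 300 ng of RNA with added ERCC spike-in RNAs. No second condition was labelled, so the data describe the make-up of the tissue and the spread between 2 mice, and no gene was tested. An exact sign-flip test over 2 libraries cannot give a two-sided p below 0.5. The gene tables held 38874862 expected counts in replicate 1 and 38160786 in replicate 2. At that depth, 3 counts on a gene with an effective length of 1000 bases correspond to 0.0925 TPM in replicate 1 and 0.0924 TPM in replicate 2. Intervals of single genes cover counting error only. Levels are TPM, the length-scaled relative abundance in the deposited gene tables, as mean ± SD with n = 2, and positions are on mm10.

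Among protein-coding genes, those of the contractile apparatus of fast muscle had the highest levels. Acta1, the skeletal muscle actin on chromosome 8 (123891769 to 123894751), came first, at 23397 ± 1008 TPM. It was followed by the myosin light chain genes Mylpf at 21782 ± 10.8 TPM and Myl1 at 12181 ± 253 TPM, and by Ckm, the muscle creatine kinase, at 11757 ± 688 TPM. Tnnt3, Tnnc2 and Tnni2, which encode the fast troponin subunits, had 8142 ± 186, 6129 ± 338 and 5597 ± 130 TPM. Tpm1 and Tpm2, the tropomyosin genes, had 7666 ± 230 and 3777 ± 520 TPM. The calcium-handling genes Pvalb and Atp2a1 had 5406 ± 423 and 5392 ± 38.4 TPM, and the glycolytic genes Aldoa and Gapdh had 4065 ± 191 and 3667 ± 186 TPM. The other members of the leading 20 were Myh4 and the mitochondrial genes mt-Co1, mt-Cytb, mt-Nd1, mt-Atp6, mt-Atp8 and mt-Nd4. Among these mt-Co1 was highest, at 9336 ± 223 TPM, and mt-Nd4 lowest, at 2811 ± 95.4 TPM. The value of mt-Atp8, 3114 ± 556 TPM, is uncertain because the gene overlaps mt-Atp6 and was listed at 0 in the second transcript table of both libraries. The order of the levels also depends on the table. In the second one Gapdh had 11483 and 12880 TPM in replicates 1 and 2, above Tnnc2 at 10725 and 9696 TPM. There mt-Atp6 had 13445 and 14362 TPM, against 3309 and 3610 TPM in the first.

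The sarcomeric myosin heavy chains were mostly of adult fast type. Myh4, which encodes the IIb chain, held 68.0% ± 4.04 (SD, n = 2) of the summed TPM of 10 such genes, and Myh1, the IIx chain, held 17.8% ± 3.24. Myh8, the perinatal chain, held 7.09% ± 0.608, above Myh2, the IIa chain, at 4.84% ± 0.879. Myh7, the slow chain, held 1.63% ± 0.441, Myh6 held 0.361% ± 0.0806 and Myh3, the embryonic chain, held 0.271% ± 0.00693. Myh13 held 0.0118%, and Myh7b and Myh15 were also low. Together Myh1, Myh2 and Myh4 made 90.6% ± 0.0754, while Myh3 and Myh8 made 7.36% ± 0.601. Myh2, Myh1, Myh4 and Myh8 lie next to each other on chromosome 11, with Myh2 starting at 67171027 and Myh8 ending at 67308634. Myh1 took 15.5% in replicate 1 and 20.1% in replicate 2, and Myh4 took 70.9% and 65.2%. These genes share long stretches of sequence, and their shares are uncertain: in the second transcript table Myh4 held 60.8%, Myh1 27.5% and Myh7 1.02%.

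**Figure D1:**
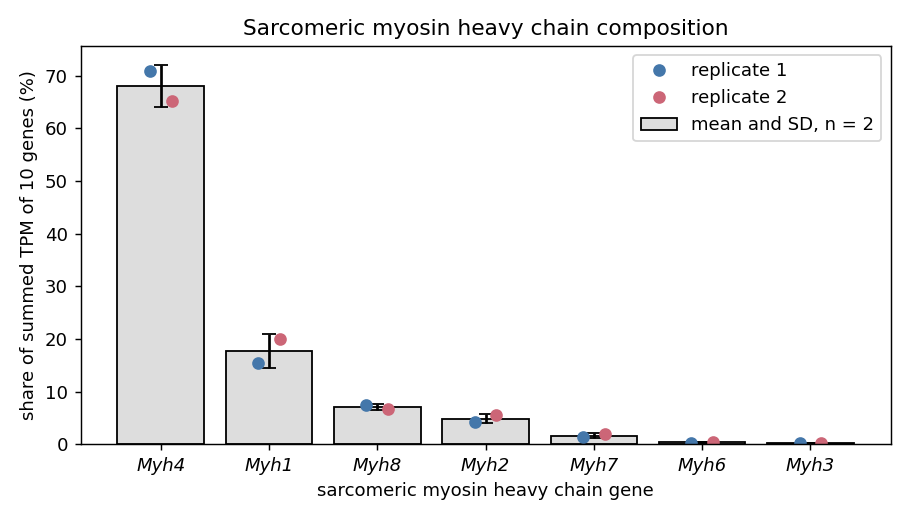
Share of the summed TPM of 10 sarcomeric myosin heavy chain genes (y axis, percent) for the 7 genes with the highest share (x axis). Bars are means, error bars SD over 2 libraries and points the libraries. Myh4 holds 70.9% in replicate 1 and 65.2% in replicate 2.

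Fast isoforms exceeded their slow counterparts in all 9 pairs and in both libraries. The median log2 ratio over the pairs was 5.90 ± 0.49 (SD, n = 2), or 59.7-fold, while the mean over the pairs was 30.7-fold and the second transcript table gave a median of 46.7-fold. The ratio was 6.50 ± 0.43 for Myl1 over Myl3, 6.34 ± 0.37 for Mylpf over Myl2 and 6.21 ± 0.19 for Atp2a1 over Atp2a2. The troponin pairs lay at 5.79 ± 0.34 for Tnnt3 over Tnnt1, 6.07 ± 0.36 for Tnni2 over Tnni1 and 5.88 ± 0.52 for Tnnc2 over Tnnc1. Smaller ratios were found for Casq1 over Casq2 (4.16 ± 0.08), Myoz1 over Myoz2 (2.47 ± 0.39) and Mybpc2 over Mybpc1 (1.06 ± 0.25). Each of these ratios exceeded its SD. Ratios are on the log2(TPM + 0.1) scale.

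Adult or muscle-type isoforms also exceeded the developmental or general type in all 13 pairs of that kind. These ratios rest on the gene tables alone, and none from the second transcript table is given for them. The largest ratios were those of Myl1 over Myl4 at 9.87 ± 0.02 and of Ckm over Ckb at 9.47 ± 0.03. Acta1 exceeded Actc1, the cardiac actin, by 3.48 ± 0.06, although Actc1 itself reached 2093 ± 2.62 TPM. Myh4 exceeded the perinatal Myh8 by 3.26 ± 0.04, and in a developmental pair Myh8 exceeded the embryonic Myh3 by 4.71 ± 0.16. Chrne, the adult acetylcholine receptor subunit, exceeded the fetal subunit gene Chrng by 3.11 ± 0.06. For metabolic enzymes the ratios were 6.45 ± 0.01 for Pgam2 over Pgam1, 3.73 ± 0.10 for Eno3 over Eno1 and 4.36 ± 0.40 for Ldha over Ldhb. For the calcium release channels the ratio was 5.33 ± 0.10 for Ryr1 over Ryr3. The cytochrome oxidase subunit pairs were closest, with 2.48 ± 0.01 for Cox6a2 over Cox6a1, 1.82 ± 0.21 for Cox8b over Cox8a and 0.38 ± 0.11 for Cox7a1 over Cox7a2.

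**Figure D2:**
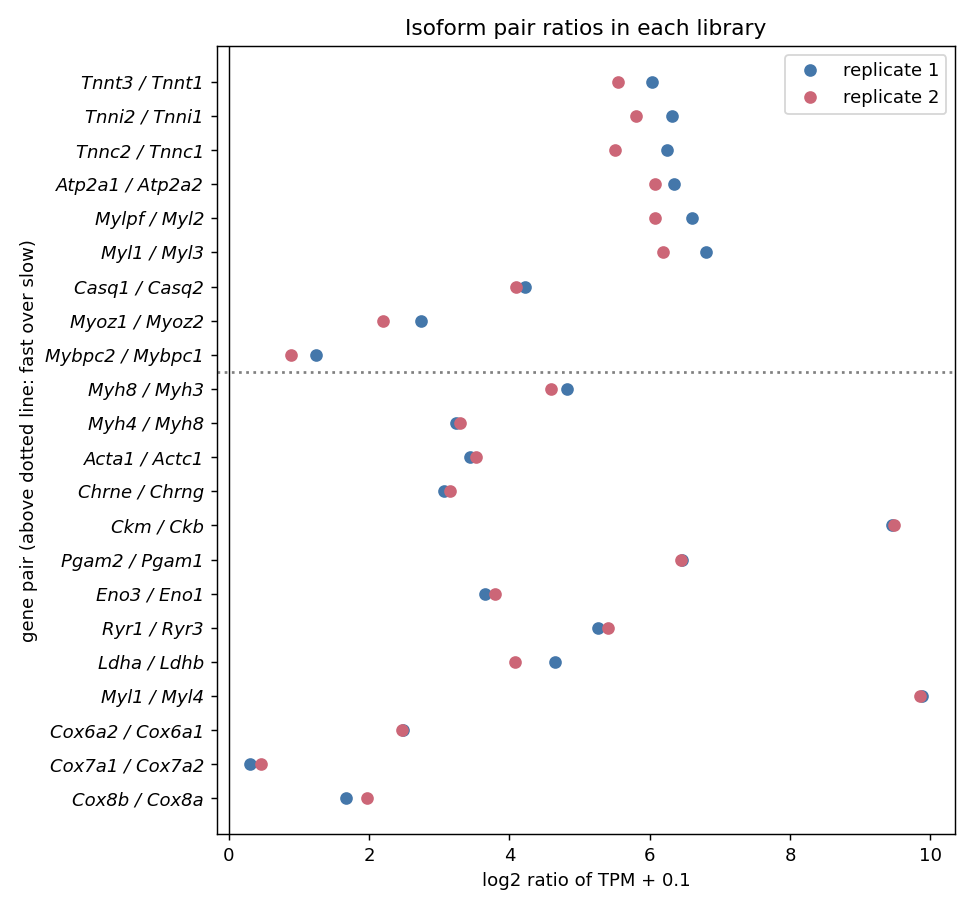
Log2 ratio of TPM + 0.1 (x axis) for 22 of the 23 gene pairs (y axis), with a point for each of 2 libraries. All ratios lie above 0, and the 9 fast over slow ratios are lower in replicate 2 than in replicate 1.

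Imprinted, cell cycle and myogenic regulator genes were detected beside the adult isoforms, and which cells of the tissue they came from was not tested. H19 and Igf2, imprinted neighbours, had 6771 ± 129 and 2665 ± 117 TPM, and the imprinted genes Rian, Meg3, Cdkn1c and Dlk1 had 1057 ± 87.0, 601 ± 177, 446 ± 31.7 and 325 ± 5.44 TPM. The mice were hybrids and alignments were on mm10, and whether reads of a parental allele were lost was not tested. Imprinted genes are read mainly from the allele of a given parent, so their levels are uncertain in this respect. Of the 27 listed imprinted genes, 23 reached 1 TPM in both libraries. All 20 cell cycle genes did so as well, at a median of 5.58 ± 0.258 TPM, led by Pcna at 17.4 ± 0.849 TPM. Of 18 myogenic regulators 17 were detected, with Mef2c at 188 ± 0.0141 TPM, while all 8 satellite cell markers were detected at a median of 5.44 ± 0.375 TPM. Of 16 genes of insulin-like growth factor and myostatin signalling 15 were detected, among them Igfbp5 at 136 ± 11.2 TPM and Mstn, the muscle growth inhibitor, at 19.8 ± 5.94 TPM. All 12 acetylcholine receptor and junction genes were detected, with Chrnb1 highest at 44.5 ± 0.0778 TPM, as were 17 of 19 excitation-contraction coupling genes.

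Among the marker lists of other cell types, the fibro-adipogenic and fibroblast list had the highest median level. Such levels depend on the genes chosen and do not measure how many cells were present. All 22 extracellular matrix genes were detected at a median of 124 ± 5.51 TPM, led by the fibrillar collagen genes Col1a1 (2060 ± 138 TPM), Col1a2 (1215 ± 49.3 TPM) and Col3a1 (1137 ± 101 TPM). Median levels were 45.4 ± 1.86 TPM for 12 fibro-adipogenic and fibroblast markers, 19.6 ± 0.629 for 9 tendon markers, 17.3 ± 1.55 for 12 endothelial markers and 17.5 ± 0.470 for 10 mural cell markers. They were 8.22 ± 0.117 TPM for macrophage and leukocyte markers, 4.73 ± 2.06 for adipocyte markers, 4.00 ± 1.18 for erythroid markers and 3.91 ± 0.523 for Schwann cell and nerve markers. None of 9 lymphocyte markers reached 1 TPM in both libraries. Of the skin markers only Krt10 did, at 2.87 ± 0.0990 TPM. Granulocyte and mast cell markers had a median of 0.465 ± 0.0212 TPM, and cartilage and bone markers 0.43 ± 0.0636. Haemoglobin genes were high for their list, with Hba-a1 at 565 ± 217 TPM. Of 12 interferon response genes 4 were detected, led by Ifi27 at 47.4 ± 0.841 TPM.

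Nuclear protein-coding genes held 75.4% ± 0.613 (SD, n = 2) of expected counts. Mitochondrial ribosomal RNA held 8.70% ± 0.671, the 7SL RNA genes Rn7s1 and Rn7s2 held 5.08% ± 0.0189 and mitochondrial messenger RNA 3.14% ± 0.0140. Genes annotated as long non-coding or TEC held 4.09% ± 0.0819, pseudogenes 2.03% ± 0.0178 and spike-ins 0.738% ± 0.00420. Genes annotated as lincRNA alone held 3.75% in replicate 1 and 3.69% in replicate 2. Without Gm26917 and H19, left out after their counts were seen, the lincRNA genes held 0.833% and 0.741%. In TPM, which divides by length, the 7SL genes took 30.0% ± 0.306 and nuclear protein-coding genes 44.0% ± 0.294. Rn7s1 and Rn7s2 had identical values and cannot be separated. The class shares depend on the table: in the second transcript table both held almost none of the estimated counts, and nuclear protein-coding genes held 81.1% ± 0.617. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were detected in both libraries, with Ddx3y at 23.7 ± 0.728 TPM, and Xist had 0.015 ± 0.00707 TPM. In all, 11322 of 22028 annotated protein-coding genes reached 1 TPM in both libraries.

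The profiles of the 2 mice were close. Across 13019 genes with at least 1 TPM in either library, Pearson's r of log2(TPM + 1) was 0.987 and Spearman's rho 0.985. These are correlations across genes, which are not independent replicates. The biological coefficient of variation, from the edgeR common dispersion over 16214 genes, was 0.103, against 0.0485 over 46 spike-in RNAs. The tables were not copies of each other: the chi-square statistic of their counts was 18.9 per degree of freedom over endogenous genes and 8.15 over spike-ins, which says nothing further about the mice. The median absolute log2 ratio of 10967 protein-coding genes with a mean expected count of 100 or more was 0.11, and for 95% of them it was at most 0.41. Of these genes 35 differed over 2-fold, 25 of them higher in replicate 2 and 10 higher in replicate 1. The balance turned with a mean expected count of 20, where 56 were higher in replicate 2 and 86 in replicate 1, and with no filter on low counts, where 834 and 1284 were.

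Early response, haemoglobin and slow-fibre genes were higher in replicate 2 than in replicate 1. Of 33 gene lists that could be compared, 10 had a median ratio apart from matched random lists at an adjusted share under 0.05, 8 of them higher in replicate 2. The percentiles and shares describe these libraries and are no test of conditions. The smallest share that 10000 random lists can give is 0.0002, and shares are adjusted over these 33 lists with the Benjamini-Hochberg method. The log2 ratio is replicate 2 over replicate 1 after TMM scaling.

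The immediate early list had a median log2 ratio of 0.85, with 18 of 19 members higher in replicate 2 (adjusted share 0.00165). Fos, Atf3, Nr4a1 and Egr1, rapidly induced transcription factor genes, were 3.70-fold, 3.33-fold, 3.41-fold and 3.09-fold higher in replicate 2. Jund, the member with the highest level, had 33.7 TPM in replicate 1 and 75.2 TPM in replicate 2, and Dusp1 had 17.1 and 27.2 TPM. Myc was the exception, at a log2 ratio of -0.09 with an interval from -0.29 to 0.10. Erythroid markers had a median of 0.86, with 6 of 6 measured members higher (adjusted share 0.00165). Among them Hba-a1 had 412 and 719 TPM, and Hbb-bs 394 and 708 TPM. The haemoglobin genes have near-identical copies, so the split between Hba-a1 and Hba-a2 is uncertain.

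All 11 slow sarcomere genes were higher in replicate 2, with a median log2 ratio of 0.54 (adjusted share 0.00165). Tnnc1 had the largest ratio, 0.70 with an interval from 0.61 to 0.79. Myl2, Mybpc1 and Myh7 had 0.59, 0.38 and 0.53. In the same library the markers of erythroid, endothelial and mural cells were higher, with medians of 0.86, 0.20 and 0.20. The 14 fast sarcomere genes had a median of 0.04 (adjusted share 0.704), with 9 higher and 5 lower, and a median of -0.01 under scaling by library totals. Sarcomeric myosin heavy chains had a median of 0.35, with 7 of 9 higher (adjusted share 0.0022), and Myh4 and Myh8 lower at -0.14 and -0.20. All 24 nuclear genes of oxidative phosphorylation were higher in replicate 2, with a median of 0.22 (adjusted share 0.00165). Of them Atp5b, Atp5a1 and Cox4i1 had 0.21, 0.21 and 0.25. The ratio of Cox8b was 0.37 in the gene table and -0.28 in the second transcript table, so its direction is uncertain. Fatty acid use genes had a median of 0.23, with 14 of 16 higher (adjusted share 0.0022), and Pdk4, which restrains glucose oxidation, had the largest ratio, 0.82, with 159 and 305 TPM.

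Vascular markers were slightly higher in replicate 2 and cell cycle genes slightly lower. Endothelial markers had a median of 0.20, with 11 of 12 higher (adjusted share 0.00283), including Flt1 at 0.43, Cdh5 at 0.20 and Pecam1 at 0.20. Mural cell markers had a median of 0.20, with 9 of 10 higher (adjusted share 0.0132), and Cnn1 and Acta2 had 0.64 and 0.36. Cell cycle genes had a median of -0.12, with 18 of 20 lower in replicate 2 (adjusted share 0.0185), among them Cdk1 at -0.40, Mki67 at -0.33 and Top2a at -0.15. Circadian clock genes had a median of -0.12 (adjusted share 0.0132) with members on both sides: Nr1d1 had -0.61 and Tef -0.31, while Per1 had 0.35. With a trend on transcript length and GC content removed, the circadian call was lost, at a median of -0.01, and the cell cycle median was -0.08, with 15 of 20 lower (adjusted share 0.0453).

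Like the fast sarcomere genes, the other 22 lists with a median did not pass, although 7 of these 22 did under at least 1 alternative. Medians below 0 were found for markers of granulocytes and mast cells (-0.17), Schwann cells and nerve (-0.13) and cartilage and bone (-0.06). They were also found for acetylcholine receptor and junction genes (-0.09), imprinted genes (-0.03) and excitation-contraction coupling (-0.02). Medians below 0 that turned above 0 with the length and GC trend removed were those of mitochondrially encoded genes (-0.01, then 0.19), extracellular matrix (-0.02, then 0.02) and fibroblast markers (-0.003, then 0.04), and that of growth factor signalling (-0.01) turned to 0.02 in the second table. Medians above 0 were found for other myosin heavy chains (0.21), interferon response (0.14), glucocorticoid and fasting response (0.10), and glycolysis and glycogen (0.07). Medians above 0 that turned below 0 under scaling by library totals were those of myogenic regulators (0.04, then -0.01), RNAs without a poly(A) tail (0.02, then -0.02), embryonic and perinatal sarcomere genes (0.01, then -0.04) and sex marker genes (0.01, then -0.03). Cell type markers above 0 were those of adipocytes (0.08), macrophages and leukocytes (0.08), satellite cells (0.07) and tendon (0.06). Adipocyte markers lay on both sides, with 6 of 11 higher in replicate 2. The median level of all 13 adipocyte markers was 6.19 TPM in replicate 1 and 3.27 TPM in replicate 2. Lymphocyte markers, skin markers and creatine kinases had fewer than 4 members with a mean expected count of 20. Ckmt2, the mitochondrial creatine kinase of muscle, had a log2 ratio of 0.51 and Ckm 0.18. Among single members, Meg3 had -0.58, Malat1, a nuclear RNA, -0.65, and Txnip -0.46.

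**Figure D3:**
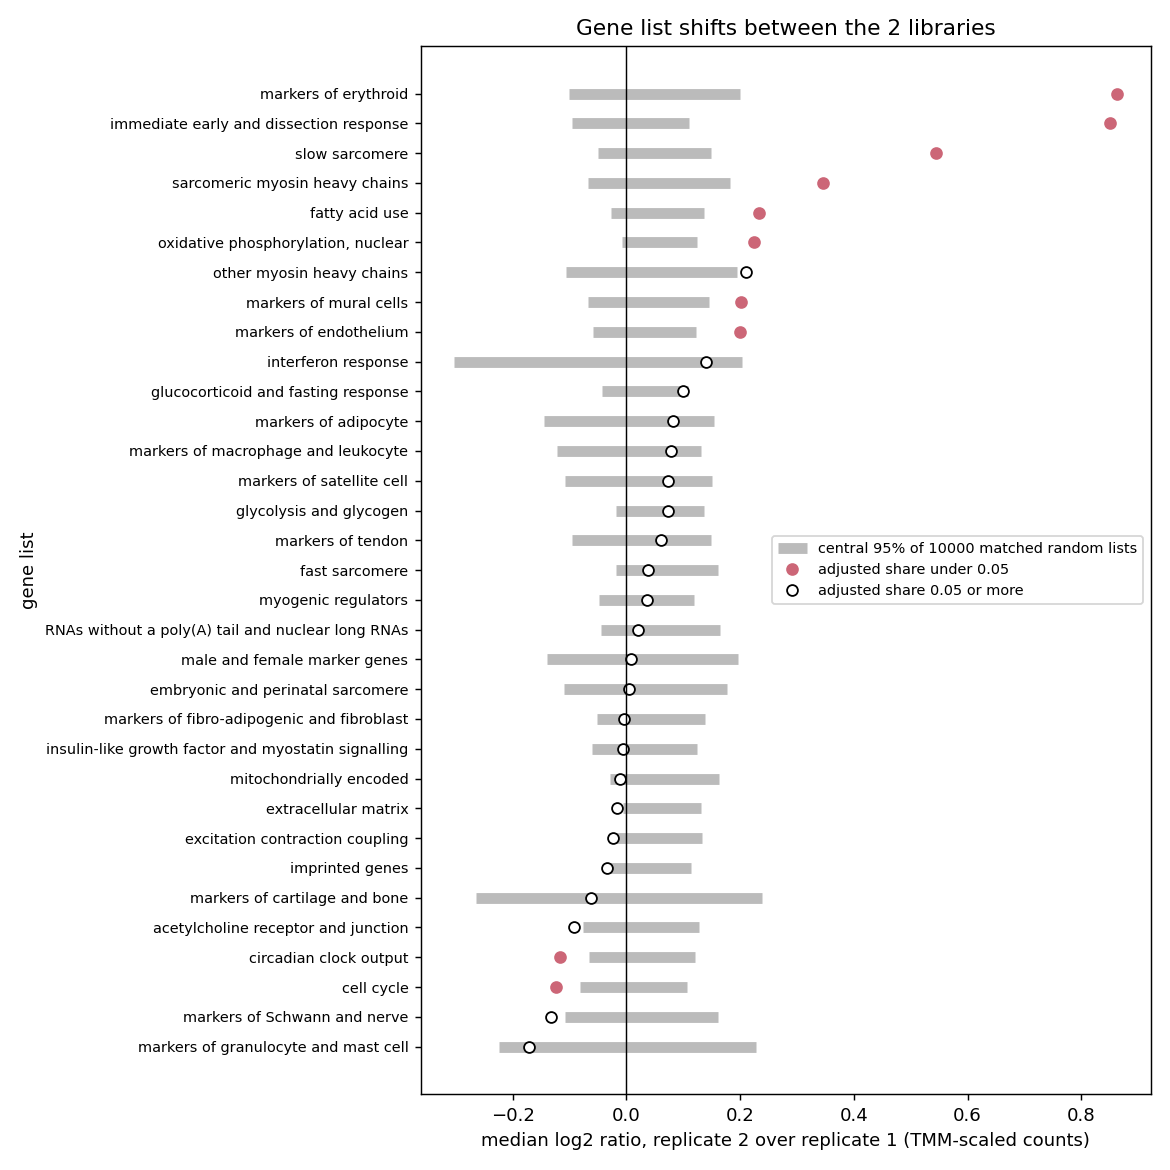
Median log2 ratio of replicate 2 over replicate 1 (x axis) for 33 gene lists (y axis). Grey bars span the central 95% of 10000 random lists matched on mean expression, and filled points mark the 10 lists with an adjusted share under 0.05.

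The single genes furthest apart were partly the same early genes. Among protein-coding genes with a mean expected count of 100 or more, the largest log2 ratio was that of Alb, the serum albumin gene on chromosome 5 (90460897 to 90476602), at 3.29 with an interval from 2.87 to 3.77, with 47 counts in replicate 1 and 442 in replicate 2. Of 10 other liver genes, 7 were also higher in replicate 2 with an interval above 0. Abra, a muscle activator of serum response factor signalling on chromosome 15 (41864076 to 41869720), had 1.95, with 24.8 and 91.4 TPM. Slc25a25, a mitochondrial carrier gene on chromosome 2 (32414487 to 32451445), had 1.90, Otud1 1.87 and Nr4a3 1.57. Fos, Nr4a1, Atf3 and Egr1 also stood among the 10 largest ratios. At the other end, Slc1a2, a glutamate transporter gene, had -1.94 and Irf4, a transcription factor gene, -1.93. Shank1, Zbed6, Xlr3b, Kcns1 and Igfn1 had -1.37, -1.29, -1.15, -1.09 and -1.04. For Nnt, Fam220a, Gm14288 and mt-Co2 the ratio differed by over 0.5 between the gene table and the second transcript table, so their ratios of 2.82, -3.68, -1.10 and -1.07 are uncertain. The direction of Fam220a turned with posterior mean counts (0.28) and that of Gm14288 in the second table (0.16).

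Each library had a second transcript table, and its gene sums differed over 2-fold from the gene-summed TPM of the first for 687 of 10962 protein-coding genes in both libraries, 649 of them higher in the second. The second table held almost none of the 7SL RNA, which took 30.0% of TPM in the first. The median log2 difference over these genes was 0.56 in replicate 1 and 0.52 in replicate 2. With both tables scaled to the same median, an alternative chosen after seeing the data, 129 genes differed, 62 of them higher in the second and 67 lower. In estimated counts 25 genes were higher in the second table and 75 lower. Across genes Pearson's r between the tables was 0.969 in replicate 1 and 0.967 in replicate 2. The genes most raised in the second table were Atp5g2, Hist1h2ad, Nnt, Cycs and Rpl27, with mean log2 differences of 5.04, 4.61, 4.03, 4.00 and 3.80. The 5 genes most lowered there, all listed at 0 in both libraries, were mt-Atp8, Rps12-ps3, Hist2h2aa2, Rpl10-ps3 and Hist1h2ao. Histone, ribosomal protein and mitochondrial genes have close copies or overlapping neighbours, so these levels are uncertain.

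The 2 tables named the same leading transcript for 14 of 21 genes. Tpm1-205 held 97.2% ± 0.240 (SD, n = 2) of Tpm1, Ryr1-202 held 91.9% ± 3.08 of Ryr1, H19-202 held 88.2% ± 1.21 of H19 and Atp2a1-201 held 85.5% ± 0.339 of Atp2a1. Tpm3-205 held 76.4% ± 7.67, Ldb3-207 70.0% ± 0.622, Bin1-205 65.9% ± 0.643, Fxr1-201 63.1% ± 0.693 and Cacna1s-204 55.0% ± 2.30 of their genes. Shares are those of the first table and could differ in the second, where Cacna1s-204 held 84.6% and Tpm1-205 77.6%. Clcn1-201 held 50.8% ± 0.721, Mef2d-201 46.7% ± 5.32, Tpm2-202 40.2% ± 1.27, Nfix-204 39.9% ± 1.68 and Mef2c-201 37.8% ± 1.60. For Tnnt3, Tnnt1, Pkm, Fhl1, Myl1, Igf2 and Meg3 the tables named different leading transcripts, so none is given.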

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

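Reads of phiX174, a sequencing control genome that no comparison used, were present in both libraries, with 48 counts in replicate 1 and 39 in replicate 2. Both lie above the limit of 3 counts that a count of 0 allows. No explanation was tested.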

How the results depend on the processing

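The removal of a length and GC trend, the tables scaled to the same median and TPM without the 7SL genes were chosen only after the data were seen. No paired analysis was possible because there was only 1 group. Leaving out a replicate leaves no value for the correlation, the coefficient of variation, the ratios and the list shifts, and with 2 libraries it says little about the stability of a mean: the share of Myh4 was 65.2% and 70.9%, the fast over slow median 5.55 and 6.25, and detected protein-coding genes numbered 11471 and 11607. The 10 lists kept their direction and their side of the threshold under DESeq2 size factors, library totals, spike-in totals, posterior mean counts, the second table, the mean over members and a mean expected count of 100. Removal of the trend ended the call of the circadian list, whose median moved to -0.01, and brought the cell cycle list near the threshold, at -0.08 with an adjusted share of 0.0453, and the cause was not tested. The number of called lists ranged from 10 to 15. Schwann and nerve markers joined under the second table, the mean (-0.52), the count of 100 and the trend removal, and glucocorticoid and fasting genes under the second table (0.16) and the trend removal (0.15). The mean of the Schwann and nerve list includes Tubb3, which was nearly absent from replicate 2, and the median was -0.13. The SD over its members was 1.43, and 0.128 with the count of 100, which leaves out Tubb3. Imprinted genes joined under the mean (-0.06) and the trend removal, mitochondrially encoded genes under the mean (-0.08), and acetylcholine receptor and junction genes (-0.09), excitation-contraction coupling (-0.03) and RNAs without a poly(A) tail (-0.05) under the trend removal. The mean of the mitochondrially encoded genes includes mt-Co2, whose uncertain ratio was -1.07 in the gene table and -0.00097 in the second table. With 6 of 13 members higher in replicate 2, that mean does not describe the list as a whole. The median of mitochondrially encoded genes, -0.01, was 0.19 with the trend removed and 0.02 in the second table. The causes were not tested. The second table gave a share of 60.8% for Myh4 and 6.08% for Myh8, and the share of Myh7, 1.63%, was 1.02% there and 1.16% by expected count, and the cause was not tested. The mean over pairs was 4.94 (30.7-fold) in place of the median of 5.90 (59.7-fold). Genes over 2-fold numbered 142 with a mean expected count of 20, 13 with 1000 and 2118 with no filter, which changes the genes counted. More of them were higher in replicate 1 than in replicate 2 with a count of 20 (86 and 56) and with no filter (1284 and 834). The coefficient of variation was 0.0940 with a mean count of 100. Pearson's r was 0.995 with no filter, 0.969 with a pseudocount of 0.1, 0.992 over protein-coding genes and 0.988 in the second table. In TPM, nuclear protein-coding genes held 44.0% and 7SL RNA 30.0%, as TPM divides by length. Genes that differed between the tables numbered 100 in estimated counts, 25 of them higher in the second, and 129 with tables scaled to the same median, 62 of them higher in the second. The ratio of Fam220a turned to 0.28 with posterior mean counts and that of Gm14288 to 0.16 in the second table, and the cause was not tested. Depth limits genes near 0.0925 TPM.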

Other observations

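The tests of scaling, of unspliced RNA and of blood cells were chosen only after the result was seen. All patterns were noticed in the same data before any test of an explanation was written, and the design names no difference between the mice.

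Tubb3 and Nefl, which encode a neuronal tubulin and a neurofilament, were nearly absent from replicate 2. Tubb3 had 44 counts in replicate 1 and 1 in replicate 2, and Nefl had 14 and 0. The Schwann cell genes Sox10 and Erbb3 had log2 ratios of 0.02 and 0.16, but 8 of the 11 measured members of their list were lower in replicate 2. The list of Schwann cell and nerve markers as a whole did not pass in the main comparison. With a mean expected count of 100, 7 of 9 members were lower, at a median of -0.13 (adjusted share 0.0355). Tubb3, Nefl, Sox10 and Erbb3 were chosen after their values were seen.

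Genes annotated as TEC, sense intronic or antisense were lower in replicate 2, with 65764 counts in replicate 1 and 48972 in replicate 2. Length and GC content are argued against as the whole cause, since TEC genes kept a median log2 ratio of -0.44 (bootstrap interval -0.51 to -0.40) without that trend. Carried-over genomic DNA stays open, as summed counts of olfactory and vomeronasal receptor genes had a log2 ratio of -0.052 with an interval from -0.27 to 0.16, and -0.59 in the second table. A shift of all long non-coding RNA stays open too, with a lincRNA median of -0.16 (bootstrap interval -0.21 to -0.11). The summed lincRNA count had a log2 ratio of 0.022 (interval 0.018 to 0.025), and -0.13 (interval -0.13 to -0.12) without Gm26917 and H19, which were left out after their counts were seen. Transcripts annotated as retained introns were lower in replicate 2 too, with 617107 counts in replicate 1 and 523810 in replicate 2. Their log2 ratio was -0.167 (interval -0.172 to -0.161), and -0.094 in the second table, against 0.026 for nuclear protein-coding genes. Whether replicate 1 held more unspliced RNA was not tested.

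Slow sarcomere genes were higher in replicate 2. Scaling cannot alter the slow minus fast median difference of 0.51 (bootstrap interval 0.32 to 0.61). Length and GC content are argued against as the whole cause, since the median was 0.57 (interval 0.42 to 0.58) without that trend. A larger share of slow-fibre RNA in replicate 2 is a candidate explanation. The 7 genes outside the list that were taken as slow-fibre genes before their ratios were computed had a median of 0.45 (interval 0.12 to 0.70). That lay above 100% of matched random lists. The members were uneven: Mb, Hspb6 and Pdlim1 had 0.71, 0.70 and 0.65, and Actn2 and Myom3 had 0.45 and 0.27. Smpx had only 0.12, and Fhl2 had 0.08 with an interval from -0.11 to 0.27. How far each of the 7 is restricted to slow fibres was not tested. Whether a larger share of slow-fibre RNA would come from fibre make-up or from neighbouring muscle was not tested either.

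Immediate early genes were higher in replicate 2. Length and GC content are argued against as the whole cause, since the median was 0.77 (bootstrap interval 0.65 to 1.14) without that trend. More unspliced RNA of the early genes in replicate 2 stays open. The TEC, sense intronic and antisense classes did not rise there, as their summed count had a log2 ratio of -0.36 (interval -0.37 to -0.34). These classes are separately annotated genes and do not measure introns of the early genes, and their fall was known when the test was chosen. Blood cells carried along stay open, with a leukocyte marker median of 0.079 (interval -0.021 to 0.33) beside an erythroid median of 0.86. The granulocyte and mast cell median was -0.17, from 4 mast cell genes with 0 of them higher in replicate 2, while the neutrophil genes S100a8 and S100a9 had only 5 and 6 and 4 and 5 counts in replicates 1 and 2.

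Alb had the largest ratio between the libraries, and liver RNA carried over into replicate 2 is a candidate source. Of 10 other liver genes listed before their counts were seen, 7 were higher in replicate 2 with an interval above 0, led by Ahsg with 9 and 110 counts, Apoa1 with 6 and 56 and Ttr with 4 and 31. Apoc3, Serpina1a and Serpina1c were not. The counts are small, and how such RNA would enter was not tested.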
